A study of Ambrosia trifida with 48 samples.

How the data were processed

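Leaf RNA of 6 giant ragweed plants, 3 GR and 3 GS, was sequenced from young and mature leaves at 4 times, in 48 libraries of paired reads of 150 bases run on 8 lanes with 6 libraries each. The labels do not assign libraries to lanes, so lanes were not tested. The authors deposited a table of FPKM per contig and library, with contig lengths, Arabidopsis matches and descriptions. The assembly, mapping and quantification programs behind it are not given in the sources used here. A second sheet held group means and was not used. The smallest FPKM steps gave back whole fragments within 0.05 for 99.6 to 99.98% of values, which gave the mapped fragments per library. Of these 63.1 to 74.7% lay on listed contigs (median 68.4%), and 6984 to 14243 contigs per library were at 0. Chi-square per degree of freedom between replicates was 22.7 to 164, so the spread exceeded counting error, and Spearman correlations within groups were 0.830 to 0.957.

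Contigs with at least 1 FPKM in at least 3 libraries were tested (45698). limma 3.58.1 in R 4.3.3 fitted 16 group means to log2(FPKM + 1) with a trended prior, 32 residual degrees of freedom and Benjamini-Hochberg adjustment within each contrast, at an adjusted p under 0.05. Contrasts compared each time with 0 min in each biotype and leaf age, the biotypes and the leaf ages at 0 min, and the GR change minus the GS change. An F test over 3 times compared mature with young responses in GR. Because every time was compared with the same 0 min libraries, lists were not overlapped between times. Gene lists were drawn from descriptions by patterns fixed in advance, 35 in all and 34 with at least 5 tested contigs, and tested by camera with a preset correlation of 0.01, and again with an estimated correlation. Some lists hold members caught by a word alone, such as DnaJ proteins among MYB factors, and such members were kept. Tables were handled with data.table (version 1.17.8), pandas 2.3.3 and numpy 2.4.6, and tests with scipy 1.17.1 and figures with matplotlib 3.10.9 in Python 3.11.15.

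Whether replicate numbers name plants was checked from the young and mature libraries. After removal of group means, libraries of one number correlated within a biotype (mean 0.538 in GR and 0.504 in GS) and those of other numbers did not (−0.269 and −0.247). In each biotype 24 of 24 libraries were closest to their own number. The fit with plants as a block was therefore run as an alternative. For the biotypes at 0 min the block was instead the replicate number, which joins different GR and GS plants. Libraries of one number did not correlate between biotypes (mean −0.0129), so that block does not stand for plants. The other alternatives were a pseudocount of 0.1, no filter, a median-ratio rescaling, the spread from the compared libraries alone and leaving out each library in turn. Chosen after seeing the data were limma-voom on recovered fragments and a fit without the 4 young libraries of GR plant 1.

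On simulated data with a single spread per contig, pooled over the groups, the test recovered 28% of 50 contigs raised 2-fold. It recovered 76% of those raised 4-fold, 90% of those raised 8-fold and 68% of 50 contigs lowered 4-fold. It called 79 of 45498 unchanged contigs. limma-voom called 24 of these and the fit of the compared libraries alone 2, which recovered 10% at 4-fold. The source of these false calls was not tested. The calls on unchanged simulated data, beside which the small counts are to be read, were 33, 29 and 18 at 15, 60 and 180 min in mature GR leaves and 16, 42 and 22 in mature GS. In young leaves they were 20, 13 and 0 in GR and 7, 10 and 3 in GS. Simulated libraries were drawn independently, without the shared deviations of plants, and with the same spread in every group. These counts therefore cover neither the pairing nor groups that vary more than others.

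Named contigs followed a rule fixed in advance: the 10 largest rises and 10 largest falls with a description, a group mean of at least 2 FPKM and no overlap between the libraries compared (not asked of response differences). Up to 4 members of each list, EPSP synthase, and at most the 2 largest rises and 2 largest falls without a description were added. Among these, the contigs printed were picked after their values were seen, mainly those whose calls held with each library left out. The EPSP synthase contigs were taken by code after the description pattern had missed them, and the 4 contigs called at 15 min as differing between biotypes were named because the count was small.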

Results

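Giant ragweed (*Ambrosia trifida*), a weed of arable fields, was sprayed with glyphosate, a herbicide that blocks EPSP synthase and with it the shikimate pathway to aromatic amino acids. Leaf RNA came from 3 glyphosate-resistant (GR) and 3 glyphosate-susceptible (GS) plants. Young and mature leaves were taken from each plant before spraying (0 min) and 15, 60 and 180 min after a dose of 0.84 kg acid equivalent per hectare. That gave 16 groups of 3 libraries, 48 in all, for the rapid response that the study's title names. The expression table listed 65623 assembled contigs of 500 to 17835 bp (median 752 bp), of which 41123 carried an Arabidopsis match, and 45698 were expressed highly enough to be tested. No chromosome positions were used, and contigs that match the same Arabidopsis gene can be fragments, alleles or near-identical copies that share reads. The FPKM steps implied 21.6 to 38.3 M mapped fragments per library (median 25.2 M). Of these 14.0 to 28.1 M lay on listed contigs. Libraries sprayed but not treated with glyphosate were not analysed here, so the herbicide, the spraying, repeated leaf sampling and the hour of day change together in every comparison with 0 min. Below, levels are mean FPKM ± SD of 3 libraries, changes are log2 differences on the log2(FPKM + 1) scale, which understates folds where a level lies below 1 FPKM, with their SE, and "rose" and "fell" mark an adjusted p under 0.05. For each contig named in a comparison with a 0 min group, between biotypes or between leaf ages all libraries of one side lay above all of the other. The rule for naming contigs required this, and chance gives it for 10% of contigs in comparisons of 3 against 3. EPSP synthase was exempt from that rule.

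The first principal component (39.8% of variance) ran mainly from young to mature leaves, and the second (18.0%) followed time after spraying. On it mature GR leaves went from 47.4, 55.3 and 49.1 at 0 min to −184, −182 and −146 at 180 min. Those of GS went from 105, 110.5 and 123 to 21.6, −19.8 and −90.7. Some libraries stood apart from their groups. The young-leaf libraries of GR plant 1 lay at −80.3, −14.2, −25.9 and 33.5 on the first component, whereas those of the other GR plants lay between −142 and −85.8. The mature GS library of plant 1 at 15 min lay at 24.8 on that component, and its group partners at 99.6 and 97.6.

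**Figure D1:**
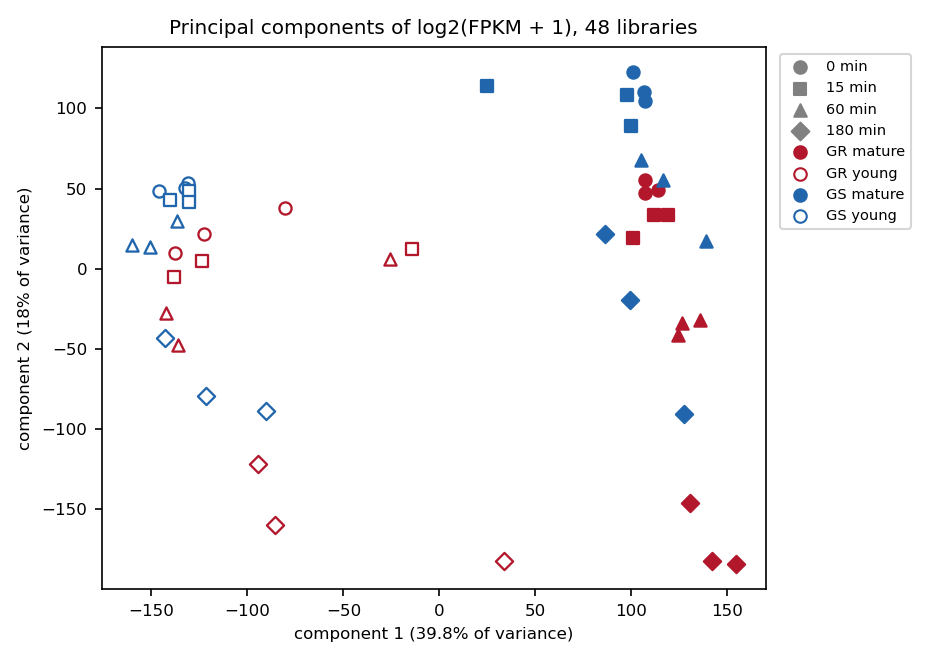
Each point is 1 of 48 libraries on the first (39.8% of variance) and second (18.0%) principal components of log2(FPKM + 1); colour gives the biotype, filled points mature and open points young leaves, and shape the minutes after spraying. The open GR points of plant 1 lie at −80.3 to 33.5 on the first component.

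Young and mature leaves before spraying were compared first, as the background for every later comparison. Some transcripts of young leaves were nearly missing from mature leaves. Germin 3 (contig21509, AT5G20630), a cell wall protein, stood at 1630 ± 842 FPKM in young GR and 1680 ± 239 in young GS leaves against 1.24 ± 1.20 and 1.24 ± 0.574 in mature ones. Histone H2A 11 (contig29229), a core component of chromatin made in dividing cells, fell from 288 ± 154 and 468 ± 72.4 FPKM in young to 1.34 ± 0.754 and 1.09 ± 0.399 in mature leaves (log2 difference −7.32 ± 0.57, adjusted p = 7.12e-13). CYCLIN D3 (contig11072), which drives entry into the cell cycle, fell by 3.53 ± 0.245. Of 110 cuticle and epidermis contigs 54 were lower in mature leaves and 18 higher (55 and 19 adjusted over the list alone, camera adjusted p = 0.00115, and adjusted p = 0.41 with an estimated correlation). Among the lower ones, 3-ketoacyl-CoA synthase 5 (contig31086) and 6 (contig32588), which lengthen the fatty acids of cuticular wax, and protodermal factor 1 (contig18382), a marker of the outer cell layer, were lower by −6.84, −5.71 and −6.68. Expansin 11 (contig26758), which loosens cell walls in growing tissue, was at 34.1 ± 15.9 and 34.2 ± 7.29 FPKM in young leaves and at 0.0150 and 0.0510 in mature ones (log2 difference −5.03). FASCICLIN-like arabinogalactan 7 (contig12428), a cell wall protein, was also lower (−4.95). Since mature leaves held little of contig31086, contig32588, contig18382 and contig26758, their log2 values depend on the added 1 FPKM and reached −9.87, −9.70, −9.44 and −9.38 in other settings.

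Higher in mature leaves were nicotianamine synthase 3 (contig46900), which makes a metal chelator, at 303 ± 88.1 and 361 ± 95.9 FPKM against 0.547 ± 0.168 and 1.5 ± 1.38. So was 1-deoxy-D-xylulose 5-phosphate reductoisomerase (contig22702), a step of plastid isoprenoid synthesis (log2 difference 7.31 ± 0.58, adjusted p = 1.15e-12). A HCO3- transporter family contig (contig58925, AT2G47160) rose by 6.86. Among the lists, 115 of 173 cell cycle and DNA replication contigs were lower in mature leaves and 12 higher (119 and 12 adjusted over the list alone, camera adjusted p = 5.36e-12, and adjusted p = 0.381 with an estimated correlation). Of 422 ribosomal protein contigs, the parts of the translation machinery, 350 were lower and 10 higher (353 and 11 adjusted over the list alone, camera adjusted p = 2.1e-30, and adjusted p = 0.274 with an estimated correlation). Plastid ribosomal protein L11 (contig53364) stood at 693 ± 56.0 in young and 90.9 ± 15.5 in mature GR leaves. Circadian clock contigs, which time gene activity over the day, went the other way, with 18 of 22 higher and 1 lower (18 and 1 adjusted over the list alone, camera adjusted p = 1.09e-07, and adjusted p = 0.274 with an estimated correlation). Pseudo-response regulator 7 (contig61978) was 1 of them (1.56 ± 0.168). Of 672 salicylate and defence contigs, mostly nucleotide-binding disease resistance proteins, 245 were higher and 37 lower (227 and 36 adjusted over the list alone, camera adjusted p = 9.58e-07, and adjusted p = 0.379 with an estimated correlation; 370 higher with plants as a block). All 4 contigs that match EPSP synthase (AT2G45300) were lower in mature leaves, contig03694 by −1.76 ± 0.415, contig55785 by −1.19 ± 0.233, contig61904 by −1.54 ± 0.278 and contig23768 by −1.03 ± 0.379. In total 23126 contigs differed, 10061 higher and 13065 lower. The median-ratio rescaling moved the median over all contigs by 0.11 and gave 12546 higher and 11324 lower, with all list medians named here keeping their sign. The call of contig23768 was lost without the young GR library of plant 3 (adjusted p = 0.0792) or the mature GR library of plant 1 (adjusted p = 0.0765).

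The biotypes were compared before spraying in each leaf age. In mature leaves, an L-galactono-1,4-lactone dehydrogenase contig (contig15036, AT3G47930), the last step of ascorbate synthesis, stood at 27.2 ± 6.19 FPKM in GR and at 0 in each GS library, at least 707-fold higher by the floor of 3 fragments over the group. A pyridoxal phosphate-dependent transferase (contig28692) was at least 510-fold higher in GR (26.2 ± 2.64 against 0). A Ribonuclease H-like contig (contig39324) had 1719 fragments in GR and 1 in GS, a ratio of 1660 (95% counting interval 297 to 65500). Cytochrome P450 83B1 (contig38509), from a family of oxidising enzymes that also acts in herbicide breakdown, had 704 fragments in GR and 2 in GS, a ratio of 339 (93.6 to 2810). Copper/zinc superoxide dismutase 3 (contig49925), which removes superoxide, was higher in GR (29.4 ± 16.5 against 0.406 ± 0.536, log2 difference 4.29 ± 0.74, adjusted p = 8.95e-05), as was an NAD(P)-binding Rossmann-fold contig (contig45868, 5.80 ± 0.456). Among the largest falls toward GR were 3 contigs matched to callose or glucan synthases, which build cell wall polymers. Glucan synthase-like 12 (contig16859) stood at 0.924 ± 0.302 against 82.8 ± 7.43 (−5.45 ± 0.178), callose synthase 1 (contig35264) differed by −4.02. Glucan synthase-like 3 (contig59217) was at 0 in each GR library and at least 267-fold lower. An unannotated contig (contig39518) had 7541 fragments in GS and 1 in GR, a ratio of 7820 (1400 to 309000). Several contigs of one match went both ways. Ubiquitin extension protein 1 was higher in GR as contig50466 (5.36) and lower as contig61120 (−4.00), and glutathione S-transferase THETA 1, a detoxifying enzyme, was higher as contig61662 (1.52) and lower as contig57060 (−1.22). The contig57060 call was lost with the 6 libraries alone (adjusted p = 0.0664).

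In young leaves 5 of these contigs kept their direction and call: contig15036 (5.04), contig28692 (5.35), contig39324 (6.14), contig16859 (−5.06) and contig35264 (−3.75). So did the contig39518 difference of −7.03 and both ubiquitin contigs (contig50466 4.61, contig61120 −5.37). Against GS groups with few fragments, the ratios in young leaves were at least 802-fold for contig28692, 1870 (517 to 15400) for contig39324 and 2720 (487 to 107000) for contig15036. Lower in GR were contig16859 by at least 858-fold and contig39518 by a ratio of 3490 (967 to 28900). Osmotin 34 (contig23137), a defence protein of the thaumatin family, was higher in GR (135 ± 54.8 against 5.60 ± 4.57, log2 difference 4.51 ± 0.706, adjusted p = 2.91e-05), as was a ribosomal protein L35Ae contig (contig52883, 4.99 ± 0.297). A GroES-like alcohol dehydrogenase contig (contig21725) was at 0 in each young GR library and at least 610-fold lower. Of the lists, none of 34 was called in mature leaves (camera with a preset correlation, and 0 with an estimated one). In young leaves the nuclear photosynthesis list was higher in GR (5 of 109 higher and 1 lower, 9 and 1 adjusted over the list alone, camera adjusted p = 8.61e-06, and adjusted p = 0.933 with an estimated correlation). Its photosystem II PSB29 contig (contig49120) stood at 67.9 ± 17.1 against 20.8 ± 1.68. Ribosomal proteins were called with a median of 0.08 (27 of 422 higher and 7 lower, 29 and 8 adjusted over the list alone, 35 and 12 with replicate numbers as a block, camera adjusted p = 0.0357, and adjusted p = 0.933 with an estimated correlation). This call was lost with a pseudocount of 0.1 (adjusted p = 0.126) and with the 6 libraries alone (adjusted p = 0.0955). The cell cycle list was called lower in GR with a median of −0.46 (3 of 173 higher and 4 lower, 3 and 4 adjusted over the list alone, 5 and 7 with replicate numbers as a block, camera adjusted p = 0.0298, and adjusted p = 0.933 with an estimated correlation), and lost with a pseudocount of 0.1 (adjusted p = 0.14). In the young library of GR plant 1 at 0 min that list lay at −0.80 against the other 2 GR plants.

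Of the EPSP synthase contigs, contig55785 was higher in mature GR leaves (13.2 ± 2.12 against 5.63 ± 2.61 FPKM, log2 difference 1.17 ± 0.329, adjusted p = 0.0208). In the same leaves contig03694, contig23768 and contig61904 differed by 0.44, 0.24 and 0.91 with adjusted p = 0.774, 0.888 and 0.176. The call of contig55785 was lost under the median-ratio rescaling (adjusted p = 0.0559), in limma-voom (0.0591), with the 6 libraries alone (0.132), and without GR plant 1 (0.0774), GR plant 3 (0.0807), GS plant 1 (0.0598) or GS plant 3 (0.163) at 0 min. In young leaves the 4 contigs differed by −0.64 to 0.49 and none passed (adjusted p of at least 0.509). The test called 3385 contigs in mature leaves, 2266 higher in GR, and 2325 in young leaves, 1160 higher. Without the young GS library of plant 1 the latter count was 1463. The rescaling moved the median of the mature comparison by −0.14 and gave 1887 higher and 1911 lower.

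In mature GR leaves at 15 min more contigs fell than rose (163 against 93), and some regulators were among the rises. Ethylene responsive element binding factor 1 (contig05232), a transcription factor of the AP2/ERF family, went from 1.13 ± 0.565 to 57.2 ± 19.3 FPKM (4.75 ± 0.689, adjusted p = 0.000204). MAP kinase kinase 9 (contig26874), part of a stress signalling cascade, rose by 3.0 ± 0.491, WRKY DNA-binding protein 40 (contig22115), a defence regulator, from 5.52 ± 0.912 to 39.7 ± 8.71, and a pathogenesis-related thaumatin contig (contig38005) by 2.54. Contigs that fell included RING/U-box proteins, which tag proteins for breakdown (contig07353 from 82.0 ± 16.6 to 16.8 ± 2.11, and plant U-box 45, contig07824, by 1.76), a cysteine-rich receptor-like kinase (contig01684, fell by 1.99) and a bHLH contig (contig38362, −1.91). Jasmonate genes, which make and relay a wound and defence hormone, were called as a list, with 1 of 86 contigs up and 1 down (4 and 1 adjusted over the list alone, camera adjusted p = 4.15e-07, and adjusted p = 0.307 with an estimated correlation). The AP2/ERF list (2 of 59 rose and 0 fell, 6 and 0 adjusted over the list alone, camera adjusted p = 7.3e-05, and adjusted p = 0.307 with an estimated correlation) was called upward. So was the NAC list (6 of 106 rose, 7 adjusted over the list alone, the same camera p-values), a family of plant transcription factors. With plants as a block the risen counts were 4 for jasmonate and 6 for AP2/ERF.

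At 15 min 256 contigs were called in mature GR leaves, 93 higher and 163 lower (703 with plants as a block, and 93 by limma-voom). The count was 81, 407, 86 and 116 without GR plant 1, 2 or 3 at 15 min or plant 1 at 0 min. It was 0 with the spread taken from the 6 libraries alone, where 2765 contigs had an unadjusted p under 0.05. In unchanged simulated data the same test called 33 contigs. The WRKY40 contig22115 call was lost in limma-voom (adjusted p = 0.0522) and that of contig38362 without GR plant 3 at 0 min (adjusted p = 0.103). In mature GS leaves at 15 min the same 2 falls stood out: contig38362 from 29.8 ± 12.6 to 4.56 ± 1.19 FPKM (−2.42 ± 0.372, adjusted p = 0.00144) and the RING/U-box contig07353 from 93.5 ± 41.9 to 23.8 ± 1.39 (−1.80 ± 0.317). In GS, ribosomal proteins had a median of 0.41 with 0 of 422 contigs past the threshold (0 adjusted over the list alone, 2 with plants as a block, camera adjusted p = 3.96e-25, and adjusted p = 0.596 with an estimated correlation). That group holds the library of plant 1 set toward young leaves on the first component, without which the median was 0.31 (camera adjusted p = 1.25e-17, and adjusted p = 0.6 with an estimated correlation). In GR their median was 0.18, also with 0 contigs (0 adjusted over the list alone, camera adjusted p = 2.98e-10, and adjusted p = 0.488 with an estimated correlation). The GS count was 159, 22 higher and 137 lower (746 with plants as a block, 37 by limma-voom, 279 after rescaling, 4 with a pseudocount of 0.1, 0 with the 6 libraries alone). It was 14, 371 and 25 without GS plant 1 or 3 at 15 min or plant 1 at 0 min. The contig07353 call was lost without plant 1 at 0 min (adjusted p = 0.0763) or at 15 min (0.0532). Of the falls 50 were shared by GR and GS, against 0.489 for independent lists, and of the rises 6 against 0.0448.

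At 60 min mature GR leaves showed a jasmonate response. Allene oxide cyclase 3 (contig33193), allene oxide synthase (contig19285) and lipoxygenase 3 (contig23996), enzymes of jasmonate synthesis, rose to 198 ± 118, 57.9 ± 7.22 and 179 ± 98.4 FPKM from 0.398 ± 0.423, 2.35 ± 1.89 and 3.03 ± 2.26. Jasmonate-zim-domain proteins 10 (contig64612) and 1 (contig19309), repressors that are themselves switched on by jasmonate, rose by 6.81 ± 0.84 (adjusted p = 7.71e-07) and 4.38 ± 0.503. Of 86 contigs in the list 36 rose and 3 fell (40 and 5 adjusted over the list alone, camera adjusted p = 5.81e-14, and adjusted p = 0.0896 with an estimated correlation). Transcription factors rose with them, WRKY40 (contig22115) to 163 ± 28.4, WRKY18 (contig45010) to 57.5 ± 8.24, the ethylene responsive factor 1 (contig05232) to 71.7 ± 16.2 and a NAC contig (contig31846) from 21.7 ± 10.8 to 844 ± 151. In the WRKY list 30 of 95 contigs rose and 1 fell (37 and 2 adjusted over the list alone, camera adjusted p = 1.21e-09, and adjusted p = 0.0896 with an estimated correlation). A mitogen-activated protein kinase kinase kinase 5 contig (contig08210) rose by 4.04 ± 0.402. In its kinase list 21 of 102 rose and 4 fell (25 and 4 adjusted over the list alone, camera adjusted p = 6.3e-06, and adjusted p = 0.231 with an estimated correlation).

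Genes near the herbicide's pathway rose as well in mature GR leaves at 60 min. Arogenate dehydratase 6 (contig13914), a late step of phenylalanine synthesis, went from 1.59 ± 0.276 to 80.2 ± 40.9 FPKM (4.83 ± 0.642, adjusted p = 2.31e-06), and cinnamyl alcohol dehydrogenase 6 (contig64863), from the lignin branch, from 7.47 ± 2.30 to 825 ± 88.6. In the shikimate list 8 of 65 contigs rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.0369, and adjusted p = 0.598 with an estimated correlation). With plants as a block 12 rose and 3 fell, and with the 6 libraries alone the list missed the threshold (adjusted p = 0.0811). Terpene synthase 04 (contig01271), which makes volatile terpenes, rose by 3.89 ± 0.47. In the trichome and terpenoid list 8 of 40 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 4.98e-06, and adjusted p = 0.169 with an estimated correlation; 16 with plants as a block). Among the largest falls were 2 contigs of an enzyme of iron uptake, ferric reduction oxidases 7 (contig29192) and 6 (contig48163), from 410 ± 98.5 to 36.6 ± 16.4 and from 883 ± 218 to 88.0 ± 40. A small subunit of ribulose bisphosphate carboxylase (contig03753), the enzyme that fixes carbon dioxide, went from 42.5 ± 7.44 to 3.34 ± 1.69. A guanylyltransferase contig matched to AT4G26850 (contig27506) fell by 3.25 and the light-signalling factor cryptochrome-interacting bHLH 1 (contig07580) by 2.86. In all 4748 contigs were called, 2792 higher and 1956 lower (8681 with plants as a block, 2624 with the 6 libraries alone, where the contig07580 call was lost at an adjusted p = 0.0587).

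In mature GS leaves at 60 min jasmonate and WRKY contigs were among the rises. Jasmonate-zim-domain proteins 10 (contig64612) and 1 (contig19309) rose by 4.71 ± 0.84 and 3.67 ± 0.503. WRKY40 (contig22115) rose from 4.13 ± 2.21 to 107 ± 87.0 FPKM, ethylene responsive factor 1 (contig05232) from 0.504 ± 0.263 to 62.0 ± 53.0 and the NAC contig (contig31846) from 14.7 ± 8.97 to 450 ± 412. A UDP-glycosyltransferase (contig04640), an enzyme class that attaches sugars to small molecules, went from 3.17 ± 1.92 to 198 ± 160 (5.27 ± 0.694, adjusted p = 2.23e-05). An EF-hand calcium-binding contig (contig50640), cinnamyl alcohol dehydrogenase 6 (contig64863) and the kinase contig08210 rose by 4.70, 4.96 and 2.78. The sulfur-starvation gene response to low sulfur 2 (contig46252) fell by 3.45 and contig27506 by 2.18. In the jasmonate list 18 of 86 rose and 0 fell (23 and 0 adjusted over the list alone, camera adjusted p = 3.85e-10, and adjusted p = 0.183 with an estimated correlation). In the WRKY list 10 of 95 rose and 0 fell (23 and 0 adjusted over the list alone, 19 with plants as a block, camera adjusted p = 1.18e-10, and adjusted p = 0.0828 with an estimated correlation). The count was 1247, 858 higher and 389 lower (2697 with plants as a block, 550 by limma-voom, 858 and 671 after rescaling, and 0 with the 6 libraries alone, where 5244 had an unadjusted p under 0.05). It was 803 and 368 without GS plant 1 or 2 at 60 min, and 759, 756 and 605 without plant 1, 2 or 3 at 0 min. The contig64612 call was lost in limma-voom (adjusted p = 0.0699). GR and GS shared 711 rises against 52.4 for independent lists and 239 falls against 16.7.

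By 180 min calcium-related contigs were among the largest rises in mature GR leaves. A calcium-binding EF-hand protein (contig34314) rose from 0.816 ± 0.216 to 653 ± 156 FPKM (8.47 ± 0.729, adjusted p = 3.99e-11), and a calcium-dependent lipid-binding protein (contig32704) from 0.694 ± 0.293 to 524 ± 194. Calmodulin-like 38 (contig39905) rose from 0.396 ± 0.371 to 266 ± 150. In the calcium signalling list 139 of 326 rose and 53 fell (142 and 53 adjusted over the list alone, camera adjusted p = 6.9e-05, and adjusted p = 0.456 with an estimated correlation). Senescence-related gene 3 (contig53638) rose by 7.22. Respiratory burst oxidases, which make superoxide at the cell surface, rose too: homologue D (contig32857) reached 7.0 ± 0.9 from 0.0693 ± 0.0603, and contig57121 reached 173 ± 55.0 from 5.49 ± 2.38. Of 18 such contigs 10 rose and 4 fell (10 and 4 adjusted over the list alone, camera adjusted p = 0.0135, adjusted p = 0.456 with an estimated correlation, and adjusted p = 0.0516 with a pseudocount of 0.1). Of 95 WRKY contigs 54 rose and 6 fell (55 and 6 adjusted over the list alone, camera adjusted p = 2.31e-10, and adjusted p = 0.206 with an estimated correlation). WRKY27 (contig48253) reached 50.9 ± 5.17 and contig62513 51.1 ± 13.8. Among ZAT-type zinc finger contigs, regulators of stress responses, 12 of 18 rose and 2 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.000337, and adjusted p = 0.399 with an estimated correlation).

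In the aromatic pathways at 180 min, mature GR leaves raised a class-II DAHP synthetase (contig37523), the first step of the shikimate pathway, from 6.07 ± 2.53 to 136 ± 23.4 FPKM, and arogenate dehydratase 6 (contig13914) to 74.3 ± 33.3. Phenylalanine ammonia-lyase 2 (contig56219), the entry to phenylpropanoids, rose from 9.03 ± 4.28 to 280 ± 132. Of 65 shikimate contigs 22 rose and 6 fell (22 and 6 adjusted over the list alone, 28 and 11 with plants as a block, camera adjusted p = 0.0397, and adjusted p = 0.679 with an estimated correlation). Of 62 phenylpropanoid contigs 21 rose and 8 fell (22 and 9 adjusted over the list alone, camera adjusted p = 0.0195, and adjusted p = 0.517 with an estimated correlation). Both directions occurred within one match. Of the contigs for hydroxycinnamoyl-CoA shikimate/quinate hydroxycinnamoyl transferase, contig07085 rose from 0.519 ± 0.309 to 78.7 ± 26.1 and contig18287 fell from 53.4 ± 5.19 to 3.07 ± 2.35. Photosynthesis fell: photosystem II light harvesting complex gene 2.3 (contig21760) from 3990 ± 486 to 131 ± 109 and light-harvesting chlorophyll B-binding protein 3 (contig16967) from 1470 ± 330 to 195 ± 103. Of 109 nuclear photosynthesis contigs 66 fell and 0 rose (69 and 0 adjusted over the list alone, camera adjusted p = 5.43e-12, and adjusted p = 0.456 with an estimated correlation). Ferric reduction oxidase 6 (contig48163), the HCO3- transporter contig (contig58925) and a B-box zinc finger with a CCT domain (contig11827) fell by 6.30, 5.61 and 5.24. Ribosomal protein contigs rose in 96 of 422 cases and fell in 8 (81 and 8 adjusted over the list alone, 189 and 17 with plants as a block, camera adjusted p = 0.000152, and adjusted p = 0.686 with an estimated correlation). One of them, contig33037, went from 11.6 ± 4.55 to 58.0 ± 12.3. The test called 16984 contigs, 8338 higher and 8646 lower.

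Mature GS leaves at 180 min raised an EF-hand contig matched to AT5G40690 (contig57550) from 0.997 ± 0.681 to 621 ± 585 FPKM (7.43 ± 0.637, adjusted p = 2.4e-10). Haemoglobin 2 (contig26402), an oxygen-binding protein, rose from 5.74 ± 1.48 to 399 ± 130 and UDP-glucosyl transferase 71B5 (contig03944) from 5.92 ± 0.586 to 395 ± 155. WRKY33 (contig42541) and WRKY27 (contig48253) rose by 4.76 ± 0.608 and 3.01 ± 0.461. In all 40 of 95 WRKY contigs rose and 0 fell (45 and 0 adjusted over the list alone, camera adjusted p = 2.4e-07, and adjusted p = 0.59 with an estimated correlation). A dehydroquinate dehydratase/shikimate dehydrogenase contig (contig39391), in the middle of the shikimate pathway, rose from 0.486 ± 0.428 to 5.99 ± 1.95. Ribosomal proteins rose in 215 of 422 cases and fell in 3 (234 and 4 adjusted over the list alone, camera adjusted p = 4.95e-13, and adjusted p = 0.748 with an estimated correlation). Their contig33037 stood at 56.1 ± 12.8 from 4.58 ± 1.46 and contig17303 at 116 ± 12.6 from 32.5 ± 4.50. Cold, circadian rhythm, and RNA binding 2 (contig48552) rose by 3.17. The HCO3- transporter contig (contig58925) fell from 284 ± 44.9 to 10.8 ± 3.42 and the light harvesting contig21760 from 3600 ± 997 to 603 ± 411. In total 16 of 109 photosynthesis contigs fell and 0 rose (13 and 0 adjusted over the list alone, 26 with plants as a block, camera adjusted p = 2.4e-07, and adjusted p = 0.838 with an estimated correlation). The count was 10696, 7137 higher and 3559 lower. The rescaling moved the median over all contigs by −0.13 and gave 4854 higher and 6142 lower. List medians became 0.72 for ribosomal proteins (0.99 before), 0.47 for WRKY factors (0.66 before) and −0.73 for photosynthesis (−0.43 before). GR and GS shared 4613 rises (1302 for independent lists) and 2908 falls (673 for independent lists).

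**Figure D2:**
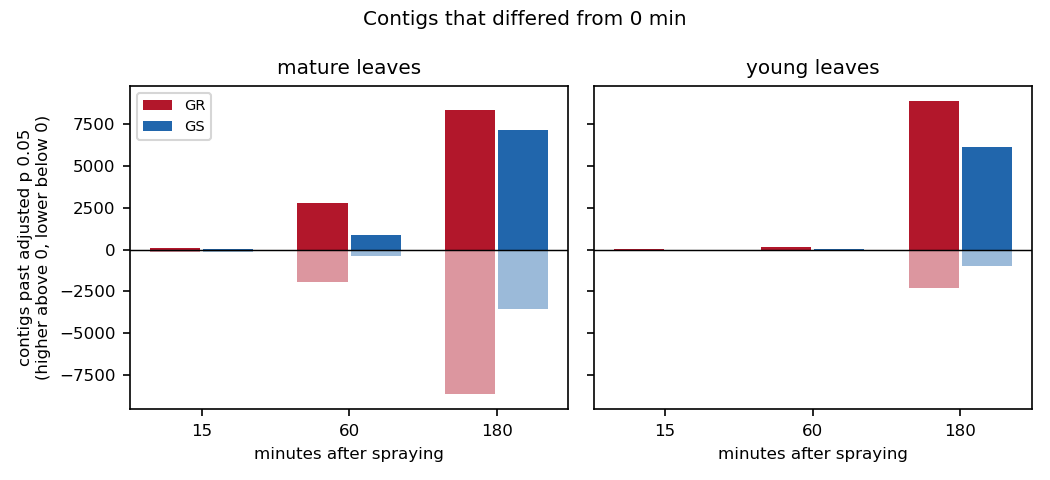
Bars count contigs past an adjusted p of 0.05 against 0 min at 15, 60 and 180 min in mature (left) and young (right) leaves, higher above 0 and lower below 0, in red for GR and blue for GS. In mature leaves the GR bars at 180 min hold 8338 higher and 8646 lower contigs and the GS bars 7137 and 3559, and in young leaves the bars before 180 min hold at most 174 contigs.

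Whether the mature-leaf response differed between biotypes was tested as the GR change minus the GS change. At 180 min the calcium-dependent lipid-binding contig32704 reached 524 ± 194 FPKM in GR and 6.25 ± 3.82 in GS (difference of changes 6.36 ± 0.967, adjusted p = 5.12e-05), and the C2H2 zinc finger contig35665 reached 97.4 ± 63.4 and 0.125 ± 0.178 (6.02 ± 0.592). Of the respiratory burst oxidase D contigs, contig39705 stood at 15.4 ± 4.88 against 0.498 ± 0.446 and contig32857 at 7.0 ± 0.9 against 0.378 ± 0.317. In their list 4 of 18 were higher and 0 lower (7 and 1 adjusted over the list alone, 7 and 1 with plants as a block, camera adjusted p = 5.15e-06, and adjusted p = 0.0646 with an estimated correlation). Of 385 contigs of heat shock proteins, which keep other proteins folded, 20 changed more in GR and 9 less (21 and 11 adjusted over the list alone, 32 and 19 with plants as a block), and the list was not called (camera adjusted p = 0.26). An Hsp70 (contig41608) went from 43.8 ± 13.2 to 346 ± 96.3 in GR and from 26.7 ± 3.87 to 29.7 ± 14.4 in GS (2.92 ± 0.519). Heat shock protein 101 (contig04919) went from 0.610 ± 0.459 to 28.4 ± 5.04 and from 0.347 ± 0.0849 to 1.31 ± 1.83. MYB15 (contig18016, 7.97 ± 2.82 against 0.149 ± 0.159 at 180 min), a regulator of phenylpropanoid genes, the WRKY contig41343, the hydroxycinnamoyl transferase contig07085, MAP kinase 9 (contig02790) and a protein kinase (contig45263) also changed more in GR, by 2.91, 3.46, 4.55, 2.51 and 5.34. At 0 min contig35665, contig39705, contig32857, contig41343 and contig18016 had at most 3 fragments in 1 or both biotypes, so their log2 values depend on the added 1 FPKM.

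Changes that were lower in GR at 180 min included nuclear factor Y subunit A7 (contig55906), a transcription factor subunit, from 14.5 ± 2.27 to 1.72 ± 0.206 FPKM in GR and from 12.2 ± 4.62 to 22.0 ± 2.85 in GS (−3.36 ± 0.321, adjusted p = 1.06e-08). The B-box contig11827 fell further in GR (−3.80), as did light-harvesting protein 3 (contig16967, −2.09). Pseudo-response regulator 7 (contig46870) went from 73.4 ± 7.43 to 54.1 ± 15.8 in GR and from 45.6 ± 6.24 to 90.2 ± 15.7 in GS (−1.43). In the photosynthesis list 11 of 109 changes were lower in GR and 0 higher (18 and 0 adjusted over the list alone, 25 with plants as a block, camera adjusted p = 7.26e-06, and adjusted p = 0.636 with an estimated correlation). The test called 2379 contigs, 1165 higher and 1214 lower (5968 with plants as a block), limma-voom 901 (214 higher, 687 lower), and after the rescaling, which moved the median over all contigs by 0.20, 1611 were higher and 574 lower. The relative list medians after rescaling were 1.04 for the oxidases and −0.42 for photosynthesis. Calls lost in limma-voom were contig32704, contig35665, contig39705, contig32857, contig41343 and contig07085 (adjusted p = 0.179, 0.117, 0.0526, 0.0647, 0.222 and 0.172), and calls lost under rescaling contig16967 (0.0611) and contig46870 (0.0681). With the compared libraries alone the calls of contig02790, contig11827, contig16967 and contig46870 were lost (adjusted p = 0.0606, 0.0755, 0.122 and 0.0601) and 475 contigs were called. The count was 1405 without GR plant 1 at 180 min, 1584 without GS plant 2 at 0 min, and 1345, 1526 and 4023 without GS plant 1, 2 or 3 at 180 min.

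At 60 min phenylalanine ammonia-lyase 1 (contig02369) went in GR from 6.99 ± 2.52 to 97.4 ± 26.1 FPKM, and stood at 32.3 ± 6.27 and 30.3 ± 16.4 in GS (difference of changes 3.90 ± 0.582, adjusted p = 0.000446). Patatin-like proteins, lipid-cleaving enzymes (contig21202 and contig22798), and an auxin-responsive GH3 contig (contig12491) changed more in GR by 3.05, 2.79 and 2.28, and a protein kinase (contig18655), at 0 in each GS library, by −1.35. The trichome and terpenoid list changed more in GR, with 2 of 40 higher and 0 lower (4 and 0 adjusted over the list alone, 4 with plants as a block, camera adjusted p = 3.06e-06, and adjusted p = 0.522 with an estimated correlation). At 60 min 83 contigs were called (187 with plants as a block, 135 with no filter, 13 with a pseudocount of 0.1, 2 by limma-voom). In limma-voom the calls of contig21202, contig22798, contig12491 and contig18655 were lost (adjusted p = 0.166, 0.313, 0.313 and 1). With the compared libraries alone 2 contigs were called, and contig02369, contig21202, contig22798, contig12491 and contig18655 were lost (adjusted p = 0.174, 0.17, 0.321, 0.311 and 0.159). The contig18655 call was lost also with a pseudocount of 0.1 (0.915). The count was 48, 50, 43, 45, 48, 54, 44, 163 and 44 without, in turn, GR plants 1 and 3 at 0 min, GR plant 2 at 60 min, GS plants 1, 2 and 3 at 0 min and GS plants 1, 2 and 3 at 60 min. At 15 min 4 unannotated contigs differed, contig29995 (−1.30), contig40472 (−1.25), contig42925 (−1.46) and contig55888 (−2.22). Their levels went from 2.27, 2.35, 3.16 and 11.1 to 0.317, 0.371, 0.487 and 1.62 FPKM in GR and were at most 0.0837 in GS, so the difference is that of GR alone and its log2 value depends on the added 1 FPKM. All 4 were lost with a pseudocount of 0.1 and in limma-voom (adjusted p = 1). Without GR plant 1 at 15 min contig29995, contig40472 and contig55888 were lost (0.0586, 0.0778 and 0.0778). Without GR plant 1 at 0 min those of contig40472 and contig55888 (0.254 and 0.0523), without GR plant 2 at 0 min contig55888 (0.0635). The contig40472 call was lost also without GR plants 2 and 3 at 15 min, GS plants 1, 2 and 3 at 0 min and GS plants 2 and 3 at 15 min (0.0777, 0.0574, 0.0702, 0.0511, 0.102, 0.187 and 0.0913). That count was 2, 7, 1 and 9 without GR plants 1 and 3 at 0 min and GR plants 1 and 2 at 15 min.

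In young leaves at 15 and 60 min the test called 35 and 174 contigs in GR and 5 and 14 in GS, and the GR count at 60 min was 1759 without plant 1 at that time. Nitrate reductases, the first enzymes of nitrate assimilation, rose in both biotypes. At 15 min nitrate reductase 1 (contig07777) went from 15.1 ± 4.34 to 86.2 ± 39.1 FPKM in GR (2.38 ± 0.4, adjusted p = 0.00627) and from 25.5 ± 1.97 to 148 ± 12.5 in GS (2.49 ± 0.4). Nitrate reductase 2 (contig06226) went from 62.3 ± 5.76 to 352 ± 55.5 in GS. FRA8 homolog (contig06745), a glycosyltransferase of cell wall synthesis, rose by 2.5 in GR and 2.66 in GS. The other 2 of 5 calls in GS were an exostosin contig (contig54850, 2.19) and a bZIP factor (contig50619, 2.17). At 60 min the nitrate reductases reached 263 ± 113 and 682 ± 304 in GR (contig07777 and contig06226) and 231 ± 63.4 and 611 ± 212 in GS. Also in young GR leaves at 60 min, the NAC contig31846 rose by 4.85 ± 0.795, jasmonate-zim-domain protein 1 (contig19309) by 3.25 ± 0.503 and a hydroxyproline-rich glycoprotein (contig30599) by 3.84. There heat shock protein 90.1 (contig60131) fell from 190 ± 66.2 to 37.3 ± 14.2. Jasmonate contigs rose in 3 of 86 cases and 0 fell (25 and 0 adjusted over the list alone, 17 with plants as a block, camera adjusted p = 1.68e-11, and adjusted p = 0.163 with an estimated correlation). In young GS leaves at 60 min, 2 unannotated contigs fell, contig35640 by 2.60 and contig53687 by 2.41.

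With the compared libraries alone limma called 0 contigs at 15 and 60 min in young GR and at 60 min in young GS leaves, and 1 at 15 min in young GS leaves. The young GR count was 35 at 15 min (72 with plants as a block, 20 by limma-voom, 15 without the 4 young libraries of GR plant 1, 20 in unchanged simulated data). Without GR plants 1 and 2 at 0 min and plants 1, 2 and 3 at 15 min it was 4, 7, 20, 8 and 19. At 60 min it was 174, 161 higher and 13 lower (1138 with plants as a block, 68 by limma-voom, 389 with a pseudocount of 0.1, 719 without those 4 libraries, and 52 higher and 19 lower after a rescaling that moved the median over all contigs by −0.11). Without GR plants 1, 2 and 3 at 0 min and plants 1 and 2 at 60 min it was 30, 89, 73, 1759 and 41. The contig07777 rise at 15 min in GR was lost without plant 1 at 0 min (adjusted p = 0.166) or 15 min (0.08) and without all 4 libraries (0.581), and the contig31846 call at 60 min in limma-voom (0.0578). In GS the counts were 5 at 15 min (9 with plants as a block, 2 by limma-voom, 7 in unchanged simulated data) and 14 at 60 min (49 with plants as a block, 8 by limma-voom, 10 in unchanged simulated data). The GS count at 15 min was 3, 2, 3 and 2 without plants 1 and 2 at 0 min and plants 2 and 3 at 15 min. At 60 min it was 5, 8, 9, 6 and 48 without plants 1, 2 and 3 at 0 min and plants 2 and 3 at 60 min. In GS at 15 min the call of contig07777 was lost without plant 2 at 0 min (0.0667) or plant 3 at 15 min (0.0646), and those of contig06226, contig54850 and contig50619 in limma-voom (0.0773, 0.217 and 0.217). With a pseudocount of 0.1 contig54850 and contig50619 were lost (0.161 and 0.959), and after rescaling contig06226 (0.0612). Without GS plants 1, 2 and 3 at 0 min and plants 2 and 3 at 15 min contig06226 was at 0.113, 0.0667, 0.15, 0.194 and 0.074. Without plants 1 and 2 at 0 min and plants 2 and 3 at 15 min contig50619 was at 0.31, 0.0667, 0.156 and 0.0646 (adjusted p). Of the 14 contigs called in young GS leaves at 60 min all 8 rises and 6 falls were called in GR too, against 0.0282 and 0.00171 for independent lists, and of the 5 rises at 15 min 4 were, against 0.00372.

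At 180 min young leaves of both biotypes raised defence genes. In GR the EF-hand contig57550 went from 0.332 ± 0.275 to 835 ± 675 FPKM (9.0 ± 0.637, adjusted p = 2.4e-12). A CC-NBS-LRR disease resistance protein (contig01636), of the class of intracellular immune receptors, rose from 0.272 ± 0.108 to 556 ± 505 and a calmodulin binding protein-like contig (contig58911) from 0.171 ± 0.0408 to 395 ± 330. CAM-binding protein 60-like G (contig06480), an activator of salicylate synthesis, rose from 0.348 ± 0.0912 to 234 ± 114. UDP-glucosyl transferase 71B5 (contig03944) rose by 7.91. Of 95 WRKY contigs 65 rose and 0 fell (69 and 1 adjusted over the list alone, camera adjusted p = 1.73e-20), and this call held with an estimated correlation (adjusted p = 0.0079). WRKY33 (contig45341) and WRKY48 (contig20843) rose by 6.14 and 4.59. Of 672 salicylate and defence contigs 298 rose and 3 fell (337 and 3 adjusted over the list alone, camera adjusted p = 6.14e-13, and adjusted p = 0.0978 with an estimated correlation). Of 102 MAP kinase contigs 50 rose and 0 fell (56 and 0 adjusted over the list alone, camera adjusted p = 4.23e-09, and adjusted p = 0.0937 with an estimated correlation), kinase kinase kinases 16 (contig33716) and 14 (contig12653) among them. Expansins A1 (contig12206) and A10 (contig51735) fell by 4.30 and 4.33. A ribosomal S10p/S20e contig (contig25413) fell from 236 ± 10.1 to 38.7 ± 15.3 and photosystem II PSB28 (contig36469) from 406 ± 82.2 to 101 ± 17.6. Of 422 ribosomal protein contigs 160 fell and 6 rose (177 and 10 adjusted over the list alone, 258 with plants as a block, camera adjusted p = 3.3e-27, and adjusted p = 0.0983 with an estimated correlation). Of 109 photosynthesis contigs 45 fell and 0 rose (51 and 0 adjusted over the list alone, camera adjusted p = 2.45e-23, and adjusted p = 0.0978 with an estimated correlation).

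In young GS leaves at 180 min contig57550 rose from 0.242 ± 0.0991 to 670 ± 204 FPKM (9.03 ± 0.637) and contig03944 from 0.894 ± 0.388 to 426 ± 14.4. SCARECROW-like 14 (contig08096) rose from 1.69 ± 0.34 to 355 ± 122, ethylene responsive factor 5 (contig50381) from 1.05 ± 0.923 to 192 ± 38.4 and the NAC contig31846 from 2.48 ± 2.07 to 297 ± 54.9. WRKY70 (contig13378), a salicylate-responsive regulator, and WRKY11 (contig15750) rose by 4.94 and 2.80. Altogether 52 of 95 WRKY contigs rose and 0 fell (61 and 0 adjusted over the list alone, camera adjusted p = 2.16e-17), a call that held with an estimated correlation (adjusted p = 0.02). A TIR-NBS disease resistance contig (contig59154) rose by 5.15. In the defence list 137 of 672 rose and 3 fell (143 and 3 adjusted over the list alone, 238 with plants as a block, camera adjusted p = 0.000526, and adjusted p = 0.593 with an estimated correlation). Heat shock protein 90.1 (contig60131) fell from 261 ± 56.6 to 22.2 ± 2.39, a chlorophyll A-B binding contig (contig50963) from 372 ± 105 to 28.2 ± 9.89, and the photosystem II contigs PSB29 (contig51264) and PSB28 (contig36469) by 1.61 and 1.61. Photosynthesis fell in 19 of 109 cases and rose in 1 (20 and 1 adjusted over the list alone, 34 with plants as a block, camera adjusted p = 5.78e-22, and adjusted p = 0.176 with an estimated correlation). Ribosomal proteins fell in 40 of 422 and rose in 8 (31 and 7 adjusted over the list alone, 79 with plants as a block, camera adjusted p = 2.16e-17, and adjusted p = 0.32 with an estimated correlation). The counts were 11181 in GR (8891 higher, 2290 lower) and 7092 in GS (6129 and 963). Rescaling moved the medians over all contigs by −0.15 and −0.19 and gave 6710 and 4124 in GR and 3101 and 2136 in GS. Relative to it the WRKY medians were 0.98 and 0.80, those of ribosomal proteins −1.02 and −0.66 and those of photosynthesis −1.05 and −0.85. With plants as a block the GS count was 11786, and without GS plant 2 at 180 min it was 4585. GR and GS shared 4611 rises against 1192 for independent lists, and 780 falls against 48.3.

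**Figure D3:**
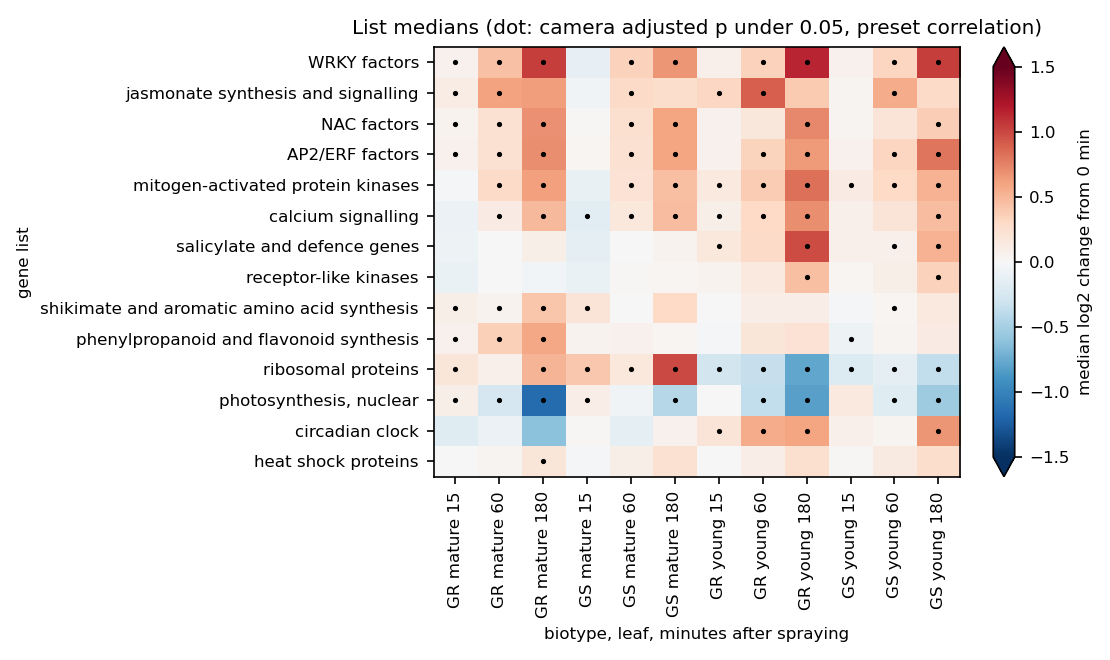
Colours give the median log2 change from 0 min of 14 gene lists in each biotype, leaf age and time, and a dot marks a camera adjusted p under 0.05 with the preset correlation. Ribosomal proteins at 180 min have medians of 0.51 and 0.99 in mature GR and GS leaves and of −0.78 and −0.37 in young ones, signs that the rescaling keeps.

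The young-leaf responses of GR and GS were tested against each other in the same way. At 180 min receptor-like and disease resistance contigs changed more in GR. A TIR-NBS-LRR contig (contig18046) went from 0.683 ± 0.494 to 42.2 ± 23.6 FPKM in GR and from 0.432 ± 0.116 to 0.929 ± 0.302 in GS (difference of changes 4.14 ± 0.608, adjusted p = 0.000132). Wall associated kinase 4 (contig02293), a receptor that senses the cell wall, went from 0.559 ± 0.127 to 29.9 ± 9.92 and from 0.0127 to 0.610 ± 0.39 (3.61). The zinc finger contig35665 went to 38.2 ± 40.7 and 0.481 ± 0.349 (4.11). Wall-associated kinase 2 (contig26100, 23.0 ± 9.64 in GR at 180 min) and a second TIR-NBS-LRR contig (contig01454, 2.52 ± 0.921) were at 0 in each young GS library at both times, so their differences of 4.09 and 1.59 are those of GR alone. An inositol trisphosphate kinase (contig28772) changed more in GS, from 6.15 ± 1.5 to 47.7 ± 20.8 against 1.40 ± 0.777 to 0.824 ± 0.276 in GR (−3.04), and ribosomal protein L35 (contig17568) differed by −1.55. Of the defence list 12 of 672 changed more in GR and 0 less (30 and 1 adjusted over the list alone, 29 and 1 with plants as a block, camera adjusted p = 4.53e-12, and adjusted p = 0.233 with an estimated correlation). Of 997 receptor-like kinases 10 changed more and 0 less (15 and 1 adjusted over the list alone, 25 with plants as a block, camera adjusted p = 0.00235, and adjusted p = 0.426 with an estimated correlation).

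The test of the young-leaf difference called 144 contigs at 180 min, 122 higher and 22 lower (329 with plants as a block, 84 after rescaling, 51 with a pseudocount of 0.1, 71 without the 4 young libraries of GR plant 1, and 0 by limma-voom, where 1592 had an unadjusted p under 0.05). Accordingly contig18046, contig26100, contig02293, contig01454, contig35665 and contig17568 had an adjusted p of 1 in limma-voom and contig28772 of 0.639. Calls of contig02293 and contig17568 were lost with a pseudocount of 0.1 (0.586 and 0.78). With the compared libraries alone 14 contigs were called, and contig01454, contig35665, contig28772 and contig17568 were lost (adjusted p = 0.0701, 0.278, 0.101 and 0.38). The count was 88, 93, 92, 86, 427, 78, 83, 85 and 79 without, in turn, GR plants 1, 2 and 3 at 0 min, GR plants 1 and 3 at 180 min, GS plants 1, 2 and 3 at 0 min and GS plant 1 at 180 min. At 15 and 60 min limma called 0 contigs, with 117 and 478 at an unadjusted p under 0.05, and limma-voom called 0 at both times.

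In GR, the mature and young responses were compared by an F test over the 3 times. Heat shock contigs were among the largest differences. An Hsp70 (contig41608) went from 43.8 to 346 FPKM in mature and from 108 to 15.1 in young leaves by 180 min (mature minus young 5.74, adjusted p = 1.43e-08). A heat shock contig (contig16989, AT5G56000) went from 9.97 to 95.7 and from 46.7 to 7.12 (5.82), and a 17.6 kDa class II heat shock protein (contig29803) from 7.75 to 908 and from 6.16 to 12.5 (5.60). In the heat shock list 75 of 385 were called (81 adjusted over the list alone), 41 of them higher in mature leaves at 180 min and 34 lower. The HCO3- transporter contig58925, at 256 FPKM in mature and 1.1 in young leaves at 0 min, differed by −5.51. An Argonaute contig (contig11532), of the small RNA machinery, went from 22.9 to 109 in mature and from 5.36 to 762 in young leaves (−4.78), and nitrate reductase 1 (contig07777) at 60 min from 251 to 163 and from 15.1 to 263 (−4.58). Of 22 circadian clock contigs 9 were called (11 adjusted over the list alone), all 9 lower in mature leaves at 180 min. Of 422 ribosomal protein contigs 114 were called (150 adjusted over the list alone), 113 of them higher in mature leaves at 180 min, and of 672 defence contigs 110 (125 adjusted over the list alone), 102 of them lower. In all 6177 contigs were called, 1821 higher and 4356 lower in mature leaves at 180 min. The median over all contigs was −0.29, and no split was rescaled.

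EPSP synthase itself was followed in 4 contigs, all taken by their Arabidopsis code AT2G45300, since the table describes them as RNA 3'-terminal phosphate cyclase/enolpyruvate transferase. In mature GR leaves at 180 min contig55785 rose from 13.2 ± 2.12 to 50.9 ± 20.4 FPKM (1.80 ± 0.329, adjusted p = 3.31e-05). There contig61904 rose from 24.8 ± 6.93 to 75.2 ± 18.4 (1.57 ± 0.393, adjusted p = 0.00158) and contig23768 from 19.2 ± 10.4 to 49.4 ± 14.5 (1.41 ± 0.536, adjusted p = 0.036). The longest, contig03694 at 1792 bp, was at 18.7 ± 10.8 and 20.9 ± 9.16 (0.25 ± 0.587, adjusted p = 0.807). The contig23768 call was lost without GR plant 1 or 2 at 0 min (adjusted p = 0.189 and 0.0753) or plant 2 or 3 at 180 min (0.0763 and 0.123). In mature GS leaves at 180 min contig55785 rose from 5.63 ± 2.61 to 11.9 ± 6.03 (0.93 ± 0.329, adjusted p = 0.0373). This call was lost under rescaling (0.158), in limma-voom (0.0982), with the 6 libraries alone (0.243) and without GS plant 1 or 3 at 0 min (0.0768 and 0.251) or plant 1 or 2 at 180 min (0.0842 and 0.279). There contig23768 and contig61904 changed by 0.77 and 0.95 (adjusted p = 0.355 and 0.078, and 0.00736 and 0.0013 with plants as a block). Without GS plant 3 at 180 min contig61904 passed (1.34, adjusted p = 0.0241). In young GR leaves at 180 min contig03694 and contig61904 changed by −1.27 and −0.78 (adjusted p = 0.118 and 0.161, and 0.00359 and 0.00719 with plants as a block). After rescaling contig61904 passed too (−1.02, adjusted p = 0.0388). In young GS leaves the 4 contigs changed by −0.50 to −0.33 with adjusted p of at least 0.484. No EPSP synthase contig was called at 15 or 60 min in either biotype or leaf age, or in any difference between GR and GS responses, where the smallest adjusted p was 0.324 (contig55785 in mature leaves at 180 min).

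A homeodomain-like contig (contig01591, AT1G01060), of a class of DNA-binding proteins, and contig10129 (AT2G46830, without a description in the table) fell in both biotypes. In young leaves contig01591 fell from 151 ± 24.8 to 12.8 ± 5.81 FPKM in GR (−3.53 ± 0.222, adjusted p = 1.59e-13), and from 136 ± 17.2 to 11.6 ± 3.06 in GS by 180 min. At 60 min it was lower in GR (−1.44), and the young GS libraries stood at 54.9, 63.7 and 62.8 FPKM, each below those at 0 min. By 180 min contig10129 fell by 5.81, 4.96, 5.30 and 4.73 in mature GR, mature GS, young GR and young GS leaves. The hour of day changed with the time after spraying here too, so these falls cannot be assigned to the herbicide.

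**Figure D4:**
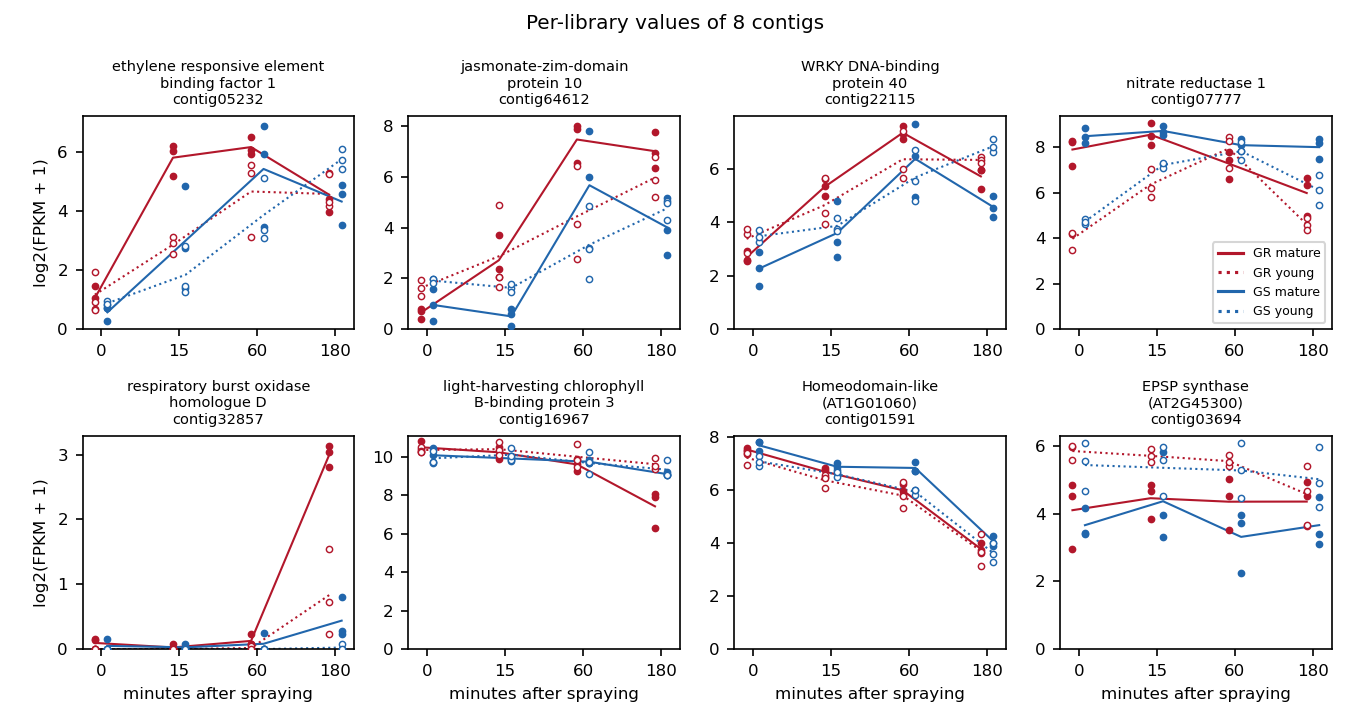
Points are log2(FPKM + 1) of each library at 0, 15, 60 and 180 min and lines join group means, for 8 contigs, with GR in red, GS in blue, filled points and solid lines for mature leaves and open points and dotted lines for young ones. In mature leaves WRKY40 (contig22115) rises by 60 min in both biotypes (4.65 in GR, 4.11 in GS), whereas respiratory burst oxidase homologue D (contig32857) reaches 7.0 FPKM at 180 min in GR and 0.378 in GS.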

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

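The tests of young-leaf and mature-leaf markers in GR plant 1, of single GS plants and the biotype in the mature response, and of copies behind the biotype differences were chosen only after the result was seen.

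The results listed here stood out because the change in one group differed from that in another by a test of the difference itself. Between the biotypes, mature responses differed for 4 contigs at 15 min, 83 at 60 min and 2379 at 180 min, and young responses for 144 at 180 min. Between the leaf ages of GR, 6177 contigs differed. Other splits of the 6 plants called at most 2, 19, 153 and 3 contigs for the biotype differences, and other splits for the leaf ages at most 77. With 10 splits these are too few for a share under 0.05. At 15 min the contigs were contig29995 (−1.30), contig40472 (−1.25), contig42925 (−1.46) and contig55888 (−2.22). List medians were 0.44 for jasmonate (camera adjusted p = 3.44e-08, and adjusted p = 0.588 with an estimated correlation) and 0.23 for WRKY factors (camera adjusted p = 6.57e-07, and adjusted p = 0.588 with an estimated correlation). At 60 min they included phenylalanine ammonia-lyase 1 contig02369 (3.90), contig21202 (3.05), contig22798 (2.79), contig12491 (2.28) and contig18655 (−1.35). List medians were 0.38 for terpenoid synthesis, 0.45 for jasmonate and 0.24 for phenylpropanoids (camera adjusted p = 3.06e-06, 3.06e-06 and 0.00734, and adjusted p = 0.522, 0.815 and 0.815 with an estimated correlation).

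At 180 min in mature leaves they included contig32704 (6.36), contig35665 (6.02), contig39705 (3.38), contig32857 (2.51), contig41343 (3.46), contig07085 (4.55), contig45263 (5.34), contig18016 (2.91), contig41608 (2.92), contig04919 (3.71), contig02790 (2.51), contig11827 (−3.80), contig55906 (−3.36), contig16967 (−2.09) and contig46870 (−1.43). List medians were 0.86 for respiratory burst oxidases, −0.76 for photosynthesis, 1.1 for ZAT-type zinc fingers, 0.25 for WRKY factors, 0.25 for phenylpropanoids, −0.58 for the circadian clock and −0.70 for the plastid and mitochondrial list, which holds mainly nuclear rRNA methyltransferases. Their camera adjusted p = 5.15e-06, 7.26e-06, 3.94e-05, 6.01e-05, 0.000646, 0.00146 and 3.96e-05 became adjusted p = 0.0646, 0.636, 0.258, 0.53, 0.478, 0.636 and 0.636 with an estimated correlation. In young leaves at 180 min they included contig18046 (4.14), contig26100 (4.09), contig02293 (3.61), contig01454 (1.59), contig35665 (4.11), contig28772 (−3.04) and contig17568 (−1.55). List medians were 0.41 for salicylate and defence and 0.10 for receptor-like kinases (camera adjusted p = 4.53e-12 and 0.00235, and adjusted p = 0.233 and 0.426 with an estimated correlation).

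The first pattern weighed is that the young leaves of GR plant 1 lay toward mature leaves on the first component. RNA of mature leaves mixed in is argued against by 280 young-leaf markers. Their median lay below the other plants by −1.28, −3.33, −3.32 and −2.16, where the share of mature markers allowed −0.016 to −0.10. Mature leaves under young labels are argued against by 36 mature markers, whose median per library was at most 6.82% of the plant's own mature level (upper quartile at most 18.3%). Leaves of an older stage stay open. The cell cycle list lay below the other 2 plants by −0.80, −1.44, −1.38 and −1.32, where those differed by −0.27 to −0.07. Any shift toward mature leaves lowers this list, so it cannot tell causes apart. Of 10 splits of the young GR libraries at 60 min, 1 other called 1875 contigs against 174, which points to a structure of the samples.

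The second pattern is the larger number of contigs called in GR (16984) than in GS (10696) mature leaves at 180 min. Fewer fragments in GS are argued against, since with all libraries thinned to the smallest total the ratio was at least 1.60 (1.59 before). A weakly responding GS plant as the whole source is argued against. On contigs called in both young responses, plants scored 1.09, 0.986 and 0.668 in GR and 0.274, 0.683 and 0.996 in GS, and the second highest GS plant (0.683) exceeded the lowest GR plant. However, without the mature libraries of the lowest GS plant at 0 and 180 min the GS count was 8953, against 12137 to 14586 in GR without 1 plant. The biotype cannot be told apart from plants, since the exact permutation p was 0.5 and 3 plants against 3 allow no p under 0.1.

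The third pattern is the difference between biotypes at 0 min. Depth is argued against, since the test of mature leaves called at least 3296 contigs with all libraries thinned to the smallest total, against 3385 before. Alleles or near-identical copies assembled apart may add to it: among 154 matched contigs called strongly in both leaf ages, 25.3% had an oppositely called contig of the same match, against a median of 13.6% in draws of uncalled contigs (7.14 to 20.1). However, strongly opposite partners were fewer than in permuted matches (3.25% against a median of 9.74%), so these tests point apart. Summing the FPKM of all contigs of a match lowered the median absolute log2 difference of the 154 from 2.73 to 0.55, and 23 still reached 2. Adding contigs lowers such differences for separate genes as well, so the explanation stays open. A difference between the biotypes themselves stays open as well, untested.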

How the results depend on the processing

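Tests by limma-voom and those without the young libraries of GR plant 1 were chosen only after the result was seen; all other alternatives were chosen before the data were examined. The cause was not tested for any change below, except that using fewer libraries leaves fewer degrees of freedom. GR and GS are followed by M (mature) or Y (young) and minutes.

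With a pseudocount of 0.1 the counts were 164 (GR M 15), 4 (GS M 15), 389 (GR Y 60), 3 (GS Y 15), and for the biotype difference 0 (M 15, with 645 at an unadjusted p under 0.05 in limma), 13 (M 60) and 51 (Y 180). With no filter the difference gave 8 (M 15) and 135 (M 60). After median-ratio rescaling the counts were 279 (GS M 15), 71 (GR Y 60) and 84 (difference Y 180), and the split in young GS leaves at 60 min went from 8 higher and 6 lower to 6 and 7 with the median over all contigs moved by −0.11. With the spread from the compared libraries alone limma gave 0 for GR M 15, GS M 15, GS M 60, GR Y 15, GR Y 60 and GS Y 60 (2765, 3577, 5244, 1447, 3866 and 4296 at an unadjusted p under 0.05; 93, 37, 550, 20, 68 and 8 by limma-voom). It gave 2624 (GR M 60), 6036 (GS M 180), 5317 (GR Y 180), 1 (GS Y 15), and 1129 and 1157 (biotypes M and Y). For the difference it gave 0 (M 15, 616 unadjusted), 2 (M 60), 475 (M 180), 1 (Y 60) and 14 (Y 180).

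With plants as a block the counts were 703, 8681, 746, 2697, 72, 1138, 9, 49 and 11786 for GR M 15, GR M 60, GS M 15, GS M 60, GR Y 15, GR Y 60, GS Y 15, GS Y 60 and GS Y 180. They were 187, 5968 and 329 for the difference M 60, M 180 and Y 180, and 12832 for the leaf ages of GR. With replicate numbers as a block, which joins different GR and GS plants, the biotypes M and Y gave 5119 and 3802. By limma-voom GS Y 15 gave 2 and the difference 0 (M 15, 424 unadjusted), 2 (M 60), 901 (M 180) and 0 (Y 180, 1592 unadjusted). Without the young libraries of GR plant 1 the counts were 15 (GR Y 15), 719 (GR Y 60) and 71 (difference Y 180).

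Leaving out 1 library at a time gave 81 to 407 (GR M 15), 3241 to 4153 (GR M 60), and 14144 to 16308 (GR M 180). In GS it gave 14 to 371 (GS M 15), 368 to 1653 (GS M 60), and 7654 to 10483 (GS M 180). Young leaves gave 4 to 34 (GR Y 15), 30 to 1759 (GR Y 60), 8464 to 11004 (GR Y 180), 2 to 5 (GS Y 15), 5 to 48 (GS Y 60), and 4585 to 5920 (GS Y 180). Further ranges were 2417 to 3006 and 1463 to 2182 (biotypes M and Y), 1 to 9, 43 to 163 and 1345 to 4023 (difference M 15, M 60 and M 180), 78 to 427 (difference Y 180). For the remaining tests they were 21502 to 22484 (leaf ages) and 4627 to 7567 (leaf ages of GR). The report names the libraries that moved a count by more than 1.5 times.

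Of 714 pairs of list and comparison, camera called 236, 242 with a pseudocount of 0.1, 210 with no filter, 221 after rescaling, 254 with the compared libraries alone and 226 with the block, and 2 with an estimated correlation. Of 275 values of named contigs none reversed, which the choice of contigs, mainly those whose calls held with each library left out, largely fixed. Calls were lost for 9 with a pseudocount of 0.1, 6 after rescaling, 59 with the compared libraries alone, 29 by limma-voom and 0 with no filter or the block, and for 43 of 2088 with 1 library left out. Depth set the floor of 3 fragments over a group used for contigs at 0.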

Other observations

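The tests by limma-voom and the 32 splits within plants were chosen only after the result was seen, and the other counts of splits were planned. Each contrast of 3 libraries against 3 has 10 splits, too few for a share under 0.05. The real count and the highest of the others were 256 and 85, 4748 and 137, and 16984 and 70 in mature GR leaves at 15, 60 and 180 min, and 159 and 248, 1247 and 78, and 10696 and 37 in mature GS leaves. In young GR leaves they were 35 and 6, 174 and 1875, and 11181 and 45, and in young GS leaves 5 and 0, 14 and 4, and 7092 and 1. The biotypes at 0 min gave 3385 and 45 in mature and 2325 and 0 in young leaves. For the young-leaf difference at 15 and 60 min all 10 splits gave 0 calls by limma (117 and 478 at an unadjusted p under 0.05 in the real split, and 0 by limma-voom). In mature GS leaves at 15 min and in young GR leaves at 60 min, 2 of 10 splits, the real one included, gave as many calls as the real one. For the leaf ages at 0 min, 1 of 100 splits, the real one, gave 23126 calls, the highest other 15716, so chance is unlikely. The same holds among the 32 splits that keep 1 young and 1 mature leaf of each plant apart, where the highest other was also 15716, with the leaves of GR plant 1 exchanged. Where replicate numbers pair plants, 4 of the 10 splits, the real one included, part all 3 pairs. The highest count among the others of these was 4 for mature GR and 13 for mature GS leaves at 180 min, and 0 by limma for the other responses to spraying.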
